A study of Homo sapiens with 4 samples.

How the data were processed

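Total RNA from 4 xenograft tumours (2 vehicle, 2 RK-287107, each from its own mouse) was labelled from 100 ng with a 3' IVT PLUS kit and hybridised to Affymetrix arrays, per the labels' protocols. The probe table used here belongs to the Human Genome U133 Plus 2.0 array. The deposited values are probe set intensities on a linear scale, all above 0, from about 3.77 to 21073. Their background correction, normalization and summarisation are not given in the sources used here. The distributions of the 4 arrays were nearly alike (medians 42.6, 42.6, 42.8 and 43.4), so the values appear to have been scaled between arrays before deposit, and a change of the whole RNA amount cannot be seen in them. No detection calls were used, and a dim value can be background. A value near the top of the scale may be compressed.

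Of 54675 probe sets, 62 controls were left out of the tests. The probe table gave 1 gene name to 41097 probe sets, several to 1801 and none to 11777. No gene was named from a probe set with several names, and one without a name is unnamed here. Of the 41097, 41043 matched a gene of the RefSeq table (assembly GRCh38.p14, used for names and gene types only) through the Entrez number, and 0 symbols changed. No genome was used, so no positions are given. Some genes of the lists have no probe set with a single name here and were not analysed.

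Values were transformed as log2(value + 16). The 40% of probe sets with the lowest mean over the 4 arrays were left out, which left 32768, of which 26543 had 1 gene name, 1274 several and 4951 none. Treated and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided, Benjamini-Hochberg, threshold 0.05) with no block. The residual degrees of freedom were 2 and the prior degrees of freedom 6.39. The labels name separate mice, so the spread is that between tumours of different mice. Fold changes are differences of mean log2(value + 16), and levels are means of the deposited intensities ± SD over 2 arrays.

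Gene lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, the one with the highest mean, and adjusted over the 27 lists with at least 3 measured members, of 28 fixed. Camera with an estimated correlation and fry, which tests whether a list moves one way, were alternatives. With an estimated correlation 0 lists were called. The lists covered Wnt feedback targets, the tankyrase and destruction complex, other tankyrase substrates, YAP targets, MYC targets, G1/S and replication, mitosis, CDK inhibitors and p53 targets, intestinal differentiation, neuroendocrine genes and hypoxia and glycolysis. They also covered the unfolded protein response and ATF4, cholesterol synthesis, interferon response, oxidative phosphorylation, glucocorticoid and circadian genes, immediate early genes, epithelial-mesenchymal transition and TGF-beta, PARP family and NAD, and reference genes. Cell type lists were fibroblast, endothelium, macrophage and granulocyte, lymphocyte, adipocyte, skeletal muscle, erythroid and keratinocyte. The lymphocyte list was included as one with little signal foreseen in this host strain, and whether its signal is background was not tested.

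The lists, the fits and list tests above and the rule for named genes were fixed before the data were examined, and later additions are named as such. The rule took the 12 genes with the largest rise and the 12 with the largest fall among called probe sets of 1 gene (a gene once, by the probe set with the smallest p) whose treated arrays both lay outside the vehicle range. It also took 14 genes of the pathway whatever their values. From each list it took up to 4 called members with the largest change (over all probe sets, else over the list alone), or the 2 with the smallest p where none was called.

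The fit was tested on simulated data, for RK-287107 against vehicle and 32768 probe sets. Variances were drawn from the variance prior of a real fit, and the noise was independent between probe sets. The single changes were placed only in probe sets at or above the median level, so recovery for dimmer ones was not tested. It recovered 27 of 70 changes of 1.5-fold, 70 of 70 of 2-fold and 60 of 60 of 4-fold. There were 11 false calls among 168, and 0 calls when nothing was changed. This recovery holds for the simulated changes only. In the real data some changes above 2-fold were not called. Examples, picked after their values were seen, are BNIP3 (log2 fold change -1.07, limma adjusted p = 0.17) and EGR1 (1.26, adjusted p = 0.14). A list shifted by -0.3 came back at -0.28 and was called by camera, but had an adjusted p of 0.16 with an estimated correlation, and 0 of 25 other lists were called. Thus the estimated correlation, taken from 2 residual degrees of freedom, missed a simulated shift of that size. The simulated genes were independent, close to the preset, so this does not show which setting suits the real data. In the real data the estimated correlation was 0.75 for cholesterol synthesis, 0.71 for G1/S and replication, 0.55 for hypoxia and glycolysis and 0.37 for interferon response. It was 0.08 for Wnt feedback targets, 0.08 for erythroid genes and -0.04 for the unfolded protein response and ATF4.

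Alternatives were a replicate block, quantile normalization, median centring, offsets of 1 and 64 and none, no intensity filter, a filter on the lowest 60%, a variance prior without trend or robust, probe sets without the suffixes for shared sequence, the mean of a gene's probe sets, each array left out in turn, an adjusted p under 0.1, and at least a 2-fold change. The fit without an offset was added after the data were seen. With 1 array left out, the lone array of its group was assumed to vary like the other group.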

Results

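Gene expression was measured in subcutaneous tumours of COLO-320DM, a human colorectal cancer cell line with amplified MYC, grown in immunodeficient NOD-SCID mice. The question was which transcripts differ after RK-287107, an inhibitor of the tankyrases. Tankyrases are poly-ADP-ribosylating enzymes that mark the scaffold protein AXIN for degradation, and AXIN limits beta-catenin dependent Wnt transcription. Mice with established tumours received vehicle or 300 mg/kg of RK-287107 daily, 5 days on and 2 days off, over 2 weeks, and tumours were collected 4 hours after the last administration. Each group held tumours of 2 mice, 1 array per tumour, so the number of arrays limits the precision of every value below. Each array gave a deposited intensity for 54675 probe sets, with medians of 42.6 and 42.6 in the vehicle group and 42.8 and 43.4 in the RK-287107 group. After the 40% dimmest probe sets were left out, 32768 were tested, and 26543 of these carried the name of 1 gene (13853 genes in all). Across these probe sets, r between arrays was 0.995 within each group and 0.990 to 0.995 between groups, a correlation over probe sets, which are not independent replicates. The first principal component held 58.6% of the variance and separated the groups.

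After RK-287107, 119 probe sets were lower and 22 were higher at an adjusted p under 0.05 (limma), on 75 and 18 named genes. The largest named falls were in the defensin gene DEFA5 and in DKK4, which encodes a secreted Wnt antagonist, and the largest named rises were in the cadherin gene CDH11, S100A6 and the type I collagen gene COL1A2. DEFA5 averaged 420.4 ± 59.2 (SD, n = 2) in vehicle tumours and 92.3 ± 37.9 (SD, n = 2) in treated tumours. At least a 2-fold change was reached by 20 of the lower and 7 of the higher probe sets, on the log2(value + 16) scale, which understates the change of dim probe sets. The treated arrays both lay below the vehicle arrays in 24.5% of tested probe sets and both above in 23.0%, where chance gives 16.7% each. An unadjusted p under 0.05 was reached by 4768 probe sets, where 1638.4 would be expected by chance. Without vehicle replicate 1 or without vehicle replicate 2, limma called 0 probe sets, with 5239 and 2701 at an unadjusted p under 0.05. Without RK-287107 replicate 2, 6 were higher and 18 lower, and without RK-287107 replicate 1, 49 were higher and 157 lower.

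**Figure D1:**
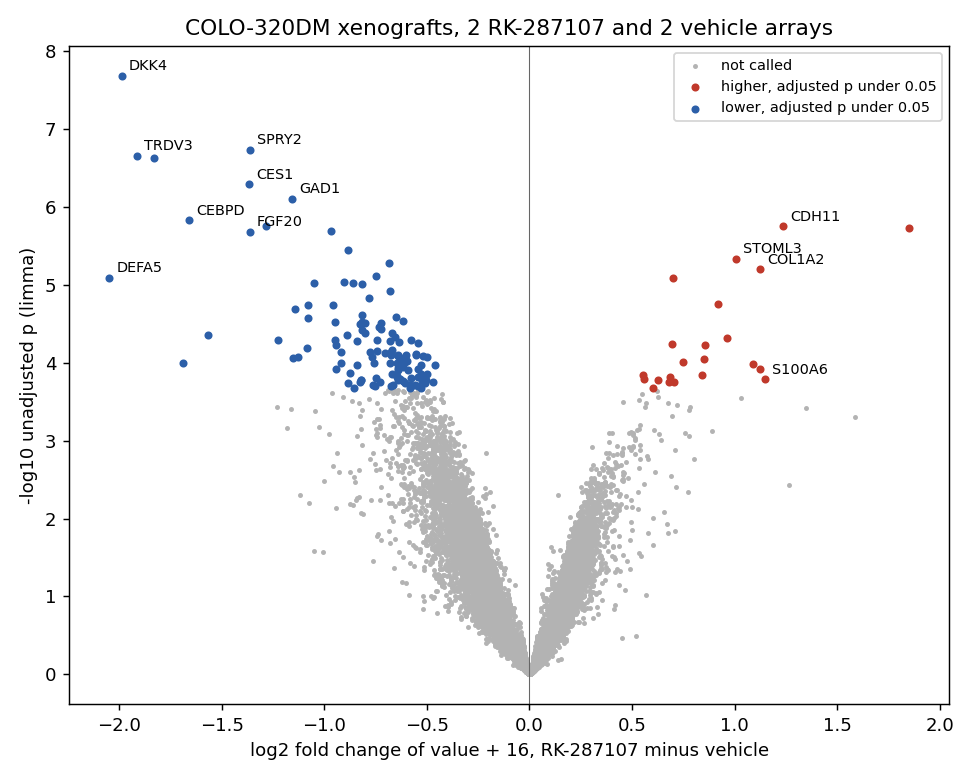
Each point is 1 of the 32768 tested probe sets, with the log2 fold change of value + 16 (RK-287107 minus vehicle, 2 arrays each) on the x axis and -log10 of the unadjusted limma p on the y axis. The 119 lower calls (blue) outnumber the 22 higher calls (red), and DKK4 has the smallest p.

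The gene group that the treatment is aimed at, feedback and target genes of Wnt signalling, was lower as a list. DKK4 fell from 202 ± 13.5 to 39.0 ± 3.05 (SD, n = 2 per group), a log2 fold change of -1.99 ± 0.098 (SE) with an adjusted p of 0.00067. DKK1, which encodes another secreted Wnt antagonist, fell from 279.5 ± 42.5 to 124 ± 24.6 (log2 fold change -1.08, adjusted p = 0.036). That DKK1 call was kept under 11 of 16 alternatives. It ended without the intensity filter, without a trend, without either vehicle array and without RK-287107 replicate 2. GAD1, the glutamate decarboxylase that makes GABA, fell from 136 ± 3.6 to 52.0 ± 1.80 (-1.16, adjusted p = 0.0043), its second called probe set gave -0.80, and the remaining one gave -0.28 without a call. Of the 30 members measured, 3 were lower and 0 higher over all probe sets, and adjusted over the list alone 13 were lower and 2 higher. Among the further members lower over the list alone, NKD1 (-0.52) and NOTUM (-0.38) encode negative regulators of the pathway. The 2 higher members, SOX9 (0.44) and ZCCHC12 (0.35), and the lower SP5 (-0.70) and TNFRSF19 (-0.75) are named here after their values were seen. The median log2 fold change of the list was -0.14 and the mean -0.26 (camera with a preset correlation, adjusted p = 3.1e-06). The adjusted p was 0.73 with an estimated correlation, so the call rested on the preset correlation. FGF20, a fibroblast growth factor gene outside the list, fell from 79.4 ± 12.2 to 21.1 ± 4.98 (-1.36 and, without an offset, -1.92, adjusted p = 0.0056).

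The drug's targets and the core of the pathway did not pass the test at the RNA level. Log2 fold changes were 0.09 for TNKS, -0.14 for TNKS2, 0.07 for AXIN1 and -0.04 for CTNNB1, the gene of beta-catenin, each on the brightest probe set. Further probe sets gave -0.12 for TNKS and -0.30 and -0.29 for TNKS2 (adjusted p = 0.26 and 0.20), without a call. The list of tankyrase and destruction complex genes had a median of 0.0032 over 24 members (mean -0.0021, adjusted p = 0.79), with AMER1 at 0.21 and GSK3B at -0.15. The list of other tankyrase substrates had a median of 0.00086 and a mean of -0.04 over 8 (adjusted p = 0.79), with AMOTL2 at -0.44 and SH3BP2 at 0.21, and none of these passed. AXIN2, a widely used Wnt target, gave -0.06 on its brightest probe set and -0.33, -0.40 and -0.40 on the other probe sets, none of them called. LEF1 gave -0.17, RNF43 -0.03, ZNRF3 -0.11 and CCND1 0.19, also without a call. MYC had one of the highest intensities, 17673 ± 73.4 in vehicle and 16827 ± 390 in treated tumours (SD, n = 2 per group), with a log2 fold change of -0.07 that did not pass the test. LGR5, a stem cell marker, lay below the intensity filter at 25.2 and 28.1. TCF7 was not analysed here.

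SPRY2 and DUSP6, which encode feedback regulators of receptor tyrosine kinase signalling, were also lower. SPRY2 fell from 133 ± 5.51 to 42.0 ± 0.191 (SD, n = 2 per group), a log2 fold change of -1.36 ± 0.088 (SE) with an adjusted p of 0.0019. DUSP6, the gene of an ERK phosphatase, fell on all 3 of its probe sets, by -0.61, -0.75 and -0.86, from 1047 ± 96.0 to 680.1 ± 25.6 on the probe set with the highest mean. That DUSP6 call was kept under 9 of 16 alternatives, and ended with quantile normalization, without the filter, without a trend and without any 1 array, while that of SPRY2 was kept under 14. In the list of immediate early and growth factor response genes, 2 of 20 members were lower over all probe sets. Adjusted over the list alone 3 were lower and 4 higher, with a list median of 0.07 and an adjusted p of 0.91. Other feedback genes of this kind did not pass, such as SPRY1 (-0.37) and DUSP5 (0.50), which are named after their values were seen.

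The remaining large falls were in genes of varied function. CEBPD, a CCAAT-binding transcription factor gene, fell from 195 ± 31.7 to 50.9 ± 9.85 (-1.66, adjusted p = 0.0056). CES1, a carboxylesterase gene, fell from 237 ± 17.9 to 82.1 ± 0.523 (-1.37, adjusted p = 0.0033). SORBS2, an actin-associated adaptor gene, fell on 3 called probe sets, the largest by -1.28, and gave 0.02 on another that was not called. The near-identical neighbours SMR3A (-1.23) and SMR3B (-1.69) were both lower, but their probes can share transcripts and the values are uncertain as separate genes. TRDV3, a T cell receptor delta variable segment, fell from 76.4 ± 15.7 to 8.47 ± 3.08 (adjusted p = 0.0019). The treated level lies below the offset of 16, and no detection calls were used, so the size of this fall is set by the offset (-1.91 with it, -3.21 without). A probe set assigned to the mitochondrial protease gene YME1L1 fell by -1.83. The 3 brightest probe sets of YME1L1 gave 0.0022, -0.16 and -0.11, and dimmer ones past the filter ranged from -0.78 (adjusted p = 0.054) to 0.09, none of them called. The assignment of the called probe set is uncertain, and -1.83 is not read as a fall of YME1L1. The glucocorticoid-inducible kinase gene SGK1 (-0.73) and the intestinal fatty acid binding protein gene FABP2 (-0.60) were lower as well. SGK1 was the 1 called member of the glucocorticoid and circadian list, whose median was 0.05 and mean -0.07 over 16 members (adjusted p = 0.61). FABP2 was the 1 called member of the intestinal differentiation list (16 members, median 0.0039, adjusted p = 0.78).

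**Figure D2:**
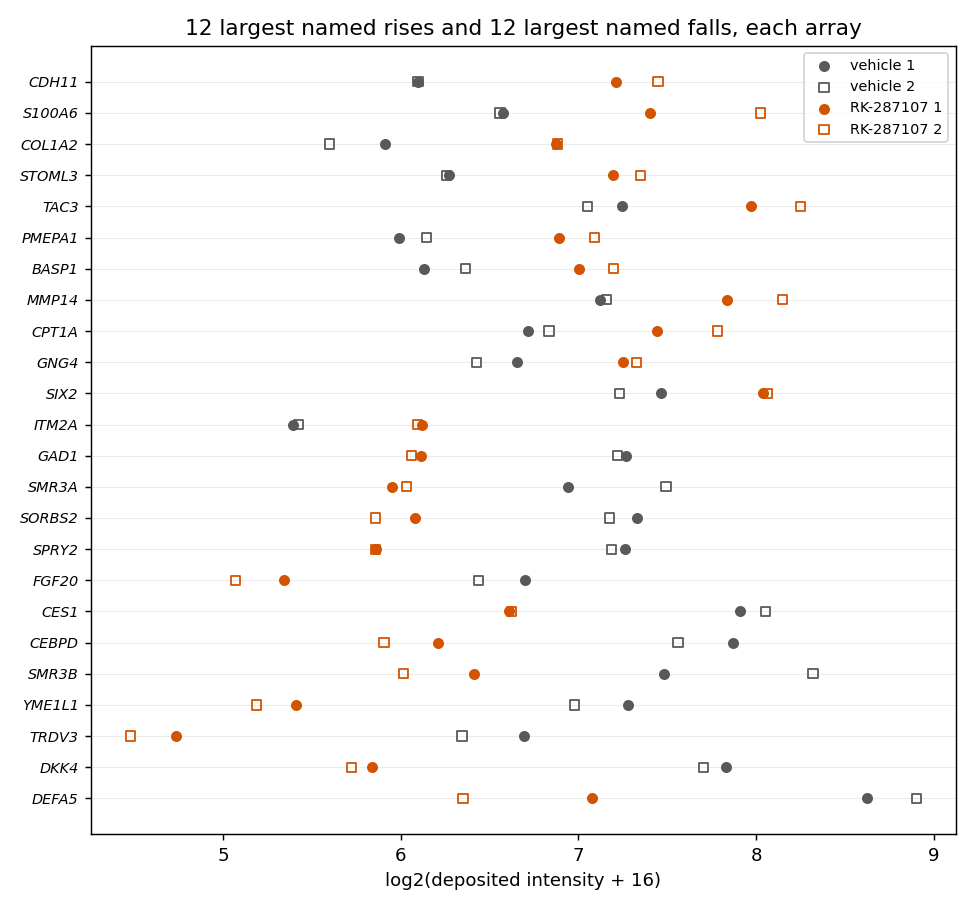
Log2 of the deposited intensity + 16 is shown on the x axis for each of the 4 arrays and for the 12 genes with the largest rise and the 12 with the largest fall (y axis). For each gene the 2 RK-287107 arrays (orange) lie on the same side of both vehicle arrays (grey), which the rule for naming these genes required.

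The rises included genes of mesenchymal cells and matrix. CDH11, a cadherin of mesenchymal cells, rose from 52.4 ± 0.0215 to 145 ± 18.6 (SD, n = 2 per group), a log2 fold change of 1.23 ± 0.11 (SE) with an adjusted p of 0.0056. COL1A2 rose from 38.4 ± 8.34 to 102 ± 0.460 (1.12, adjusted p = 0.013), and MMP14, a membrane-bound matrix metalloprotease gene, rose from 125 ± 2.44 to 240.3 ± 39.0 (0.85, adjusted p = 0.037). Each of these calls came from 1 probe set. A second CDH11 probe set gave 0.20, 2 further MMP14 probe sets gave 0.14 and 0.15, and none of these passed. The other COL1A2 probe sets lay below the intensity filter and gave 0.04 and 0.16. The called probe sets of CDH11, COL1A2 and MMP14 carry suffixes for shared sequence, so the fit without such probe sets did not include them. The tumours also hold mouse host cells, whose RNA is seen on a human array only as far as it cross-hybridises. The fibroblast list had a median log2 fold change of 0.11 over 15 members (adjusted p = 0.055), with 1 member higher over all probe sets, and 3 higher and 1 lower adjusted over the list alone. The macrophage and granulocyte list had a median of 0.10 over 11 members (adjusted p = 0.10), and the endothelial list had 0.06 over 9 (adjusted p = 0.78). Adjusted over the list alone, the macrophage genes SPI1 (0.53) and AIF1 (0.45) were higher and PTPRC (-0.40) was lower, while the endothelial CLDN5 (-0.31) and TEK (0.15) did not pass. The fibroblast list passed under 5 of 16 alternatives: without vehicle replicate 2 (adjusted p = 0.0077), without RK-287107 replicate 1 (0.013), with no intensity filter (0.017), with a replicate block (0.028) and with median centring (0.042). It did not pass with the lowest 60% left out (median 0.05, adjusted p = 0.54), and without vehicle replicate 1 (0.06, adjusted p = 0.31) and without RK-287107 replicate 1 (0.06) its median was lower. The macrophage list passed without RK-287107 replicate 1 (median 0.12) and with no intensity filter (adjusted p = 0.031). With an estimated correlation neither list passed under any of these settings (adjusted p = 0.64 for each with no intensity filter).

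Other named rises were in neuropeptide, signalling and metabolic genes. TAC3, which encodes the neurokinin B precursor, rose from 126 ± 13.6 to 262 ± 38.0 (0.96, adjusted p = 0.032). PMEPA1, a TGF-beta induced gene, rose from 51.2 ± 5.05 to 111 ± 12.5 (0.92, adjusted p = 0.021), and a second probe set at 0.53 was not called. S100A6, a calcium-binding protein gene, rose from 78.8 ± 0.781 to 199 ± 64.4 (1.15, adjusted p = 0.046). This S100A6 call was kept under 9 of 16 alternatives. It ended with quantile normalization, an offset of 64, no intensity filter and no trend, and without either vehicle array or RK-287107 replicate 2. The log2 fold change was 1.01 for the stomatin family gene STOML3, 0.85 for BASP1 and 0.84 for CPT1A, which acts in the import of fatty acids into mitochondria. The other BASP1 probe set gave -0.04 (adjusted p = 0.84), and with the mean of a gene's probe sets the calls of BASP1, SIX2 and MMP14 ended. The log2 fold change was 0.75 for the G protein gamma subunit gene GNG4, 0.70 for the homeobox gene SIX2 and 0.70 for ITM2A. Their other probe sets past the filter gave 0.51 and 0.51 for GNG4, 0.38 for SIX2 and 0.50 for ITM2A, and that of CPT1A gave 0.39, none of them called. The SIX2 call was kept under 8 of 16 alternatives, and those of GNG4, CPT1A and BASP1 under 10 of 16 each. The largest rise of all called probe sets, from 207 ± 25.5 to 799 ± 190.2 (1.85, adjusted p = 0.0056), was on a probe set with no gene name here. The list of neuroendocrine genes, to which none of these belongs, had a median of -9.8e-06 and a mean of 0.05 over 12 members (adjusted p = 0.81), and PAX6 (0.27) and CHGB (0.30) did not pass.

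Hypoxia and glycolysis genes were lower as a list, and 1 vehicle tumour set much of that difference. Over 28 members the median was -0.24 and the mean -0.31 (camera, adjusted p = 4.6e-07), and the adjusted p was 0.85 with an estimated correlation. No member passed over all probe sets. Adjusted over the list alone, 7 were lower, among them the mitophagy gene BNIP3 (-1.07), the pyruvate dehydrogenase kinase gene PDK1 (-0.86) and ANKRD37 (-0.82), and 1 was higher, the lysyl oxidase gene LOX (0.76). The list's median deviation from the mean of the 4 arrays was 0.28 on vehicle replicate 2, against -0.07 on vehicle replicate 1, -0.08 on RK-287107 replicate 1 and -0.22 on RK-287107 replicate 2. Without vehicle replicate 2 the median was -0.10 and the call ended (adjusted p = 0.10).

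Interferon response genes were lower as a list, with a median of -0.20 over 22 members (camera, adjusted p = 3.1e-06; adjusted p = 0.77 with an estimated correlation). The 1 member lower over the list alone was DDX60 (-0.35), and none passed over all probe sets. Genes of the unfolded protein response and of the ATF4 programme had a median of -0.08 over 24 members (adjusted p = 0.0052, and 0.73 as the adjusted p with an estimated correlation). Its members with the smallest p, HERPUD1 (-0.42) and CTH (-0.41), did not pass. Both lists passed without each of the 4 arrays in turn, but narrowly without vehicle replicate 1 (adjusted p = 0.049 for each). The interferon median was then -0.099, against -0.26 without vehicle replicate 2, and its deviation from the mean of the 4 arrays was 0.17 on vehicle replicate 1 and -0.01 on vehicle replicate 2. The median of the unfolded protein response list was -0.14 without vehicle replicate 1.

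Cholesterol synthesis genes had a median of -0.14 over 19 members (camera, adjusted p = 0.010; adjusted p = 0.87 with an estimated correlation), and the values of STARD4 (-0.48) and SC5D (-0.28) did not pass. Without vehicle replicate 1 the median was 0.058 (adjusted p = 0.61), and without RK-287107 replicate 2 it was -0.05 (adjusted p = 0.11). Genes of the G1/S transition and replication were higher as a list, with a median of 0.10 over 25 members (adjusted p = 0.014; adjusted p = 0.87 with an estimated correlation), and GINS2 (0.33) and CDT1 (0.23) did not pass. That call ended without vehicle replicate 2 (median 0.014, adjusted p = 0.89) and without RK-287107 replicate 2 (0.10, adjusted p = 0.29), and with all 4 arrays when suffixed probe sets were left out (adjusted p = 0.060). Erythroid genes, a list of 5 measured members, had a median of 0.17 (adjusted p = 0.022; adjusted p = 0.73 with an estimated correlation), and HBB (0.31) and CA1 (0.20) did not pass. It was not called without vehicle replicate 1 (adjusted p = 0.28), without RK-287107 replicate 2 (adjusted p = 0.11) or without suffixed probe sets (3 members, adjusted p = 0.27).

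**Figure D3:**
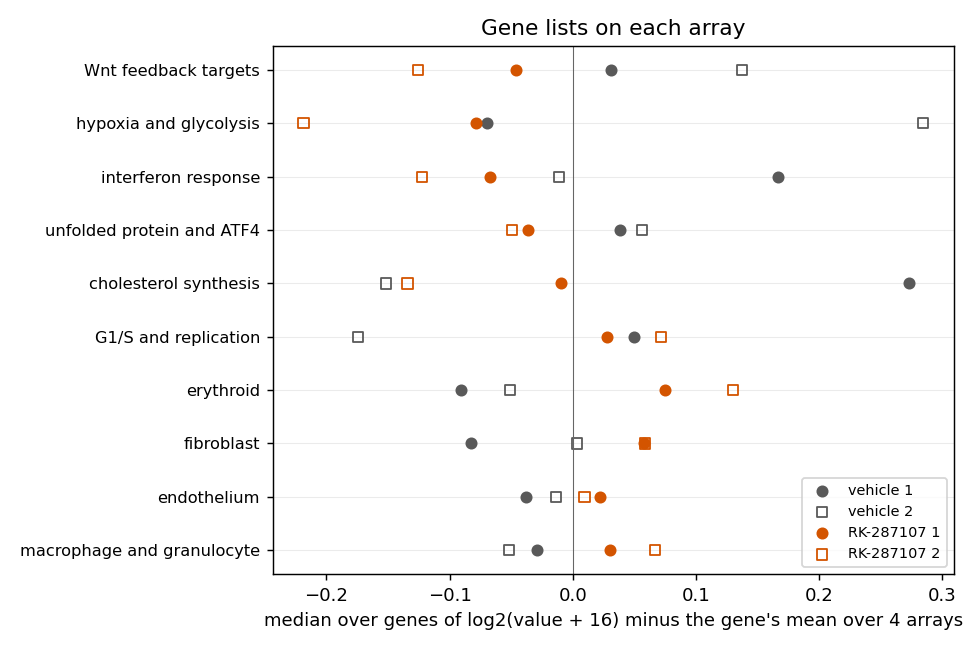
For 10 gene lists (y axis), the x axis gives the median over genes of log2(value + 16) minus the gene's mean over the 4 arrays, 1 point per array. The hypoxia and glycolysis list is at 0.28 on vehicle replicate 2 and at or below -0.07 on the other 3 arrays, while the Wnt list is above 0 on both vehicle arrays and below 0 on both RK-287107 arrays.

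Proliferation and growth lists other than G1/S did not pass with all 4 arrays. MYC targets had a median of 0.03 over 28 members (adjusted p = 0.75), with LDHA at -0.22 and CDK4 at 0.23. Mitotic genes had -0.02 over 28 (adjusted p = 0.30), with CENPE at -0.27 and HMMR at -0.23. They passed without RK-287107 replicate 1 (median -0.08), though not with an estimated correlation, and without RK-287107 replicate 2 their median was 0.04. CDK inhibitors and p53 targets had -0.02 over 18 (adjusted p = 0.44), with CDKN1C at -0.30 and GADD45A at -0.41. YAP targets had a median of 0.05 and a mean of -0.02 over 13 members (adjusted p = 0.96), with RBMS3 at 0.18. None of these genes passed over all probe sets. Oxidative phosphorylation genes had a median of -0.03 over 24 members (adjusted p = 0.055), with UQCRC2 at -0.21 and SDHD at -0.18. They passed under 4 of 16 alternatives: without vehicle replicate 2 (median -0.06), with no intensity filter (adjusted p = 0.016), with median centring (0.035) and with quantile normalization (0.041). With an estimated correlation they passed under none of these (adjusted p = 0.64 with no filter, 0.83 with median centring and 0.78 with quantile normalization). Genes of epithelial-mesenchymal transition and TGF-beta response had 0.0068 over 16 (adjusted p = 0.78), and MMP2 (-0.67) and TAGLN (0.33) in it did not pass. PARP family and NAD genes had -0.07 over 16 (adjusted p = 0.44), with TIPARP at 0.29 and PARP3 at -0.26. Reference genes had a median of 0.0097 and a mean of -0.02 over 13 (adjusted p = 0.78), with PGK1 at -0.27 and PPIA at 0.09. Among cell type lists, the median was 0.02 for lymphocytes over 9 members (adjusted p = 0.81; CD8A -0.22, CD3E 0.16) and -0.05 for adipocytes over 7 (adjusted p = 0.50; PPARG -0.10, CFD -0.11). For skeletal muscle it was 0.09, with a mean of -0.0022, over 4 members (adjusted p = 0.81), with ACTA1 at -0.34 and TNNT3 at 0.16. The keratinocyte list had 2 measured members and was not tested. Its members KRT10 and LORICRIN gave 0.07 and 0.12.

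RNA quality differed little between arrays. The ratio of 3' to 5' control signal ranged from 1.05 to 1.08 for GAPDH and from 1.30 to 1.35 for ACTB, with log2 differences between group means of 0.02 and -0.01.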

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

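The fit without an offset was chosen after the data were seen. The Wnt list was called under each of the 16 other fits, with medians from -0.20 to -0.09 and adjusted p from 3.8e-08 to 0.00021. Its median of -0.14 was not called with an estimated correlation (adjusted p = 0.73) or by fry (adjusted p = 0.25), and these called 0 and 0 of the 27 lists, against 7. A simulated shift of -0.3 was missed with an estimated correlation too, but the simulated genes were independent of each other. Without each array in turn the number of called lists ranged from 4 (without RK-287107 replicate 2) to 10, and the Wnt median from -0.20 to -0.09. The cholesterol synthesis median turned to 0.058 without vehicle replicate 1 and was -0.34 without vehicle replicate 2. A further 54 values not called under either setting changed sign, none above 0.08 in size after the change and at most 0.19 before it. That largest one was CCND1, at -0.03 without RK-287107 replicate 1.

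The counts of 22 higher and 119 lower probe sets moved most. Quantile normalization gave 12 and 67, no intensity filter 7 and 46, a variance prior without trend 8 and 38, and the mean of a gene's probe sets 16 and 52. The last tested 13853 genes and no filter tested 54613 probe sets, against 32768. The cause of these moves was not tested. An adjusted p under 0.1 gave 65 and 390, and at least a 2-fold change gave 7 and 20. Without each array in turn the counts ranged from 0 to 49 higher and from 0 to 157 lower. Fits without either vehicle array had 4.57 and 4.54 prior degrees of freedom against 6.39. Median centring, the offsets, the robust prior, the lowest 60% left out and probe sets without suffixes stayed within 1.5 times of both counts.

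Of the 28 named genes called, 28 kept their call with median centring or the robust prior, 24 with the mean of a gene's probe sets (BASP1, MMP14, SIX2 and YME1L1 lost), 22 with quantile normalization and 16 each with no filter or no trend. Without either vehicle array 0 of the 27 still tested kept it, without RK-287107 replicate 1 24 of 28, and without RK-287107 replicate 2 13 of 28. None changed direction under these settings. By gene, calls were kept least often for SIX2 (8 of 16 alternatives), MMP14 (9 of 15) and S100A6, SGK1 and DUSP6 (9 of 16 each). SMR3B kept its call under 10 of 16 and FABP2 under 10 of 15.

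With the replicate number as a block (paired fit), 148 probe sets were higher and 935 lower, including all 141 called without it. With 2 pairs the arrays share only a number, and the deviations of the arrays numbered 1 from their group means correlated at 0.129 across probe sets. Intensities near background, with no detection calls, limit what can be said of dim probe sets.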

Other observations

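The tests of a lower share of tumour cells, of other splits and of ERK genes were chosen after results were seen; the others were fixed before their results were seen. The genes of the next paragraph, and TIMP3, OLFML2B, BGN, MAFF and EGR1 below, were chosen after their values were seen.

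Genes outside the lists were also lower after RK-287107. The insulin-like growth factor binding protein gene IGFBP5 fell from 851 ± 55.3 to 381 ± 105 (SD, n = 2 per group; log2 fold change -1.15, adjusted p = 0.037) and by -0.76 on a second called probe set. CAV1, which encodes the membrane coat protein caveolin 1, fell by -0.96 and -0.58 on 2 called probe sets, and the kinase gene SYK by -0.92 and -0.82. The AP-1 gene FOSL2 (-0.88), the metalloprotease gene MMP11 (-0.83), the hormone precursor gene POMC (-0.76) and the bone and lineage transcription factor gene RUNX2 (-0.67) were lower as well. Further probe sets of some of these were not called, with values from -0.84 to -0.20 for FOSL2, -0.74 and 0.13 for MMP11 and from -0.57 to 0.08 for RUNX2. The long non-coding RNA MALAT1 was lower on 3 called probe sets (-0.54, -0.62 and -0.64), while others of its probe sets gave values from -0.43 to 0.01 without a call. IGFBP7 fell by -1.14 on 1 probe set, and its other, brighter probe set gave 0.20 without a call.

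The stromal genes COL1A2, CDH11, MMP14, TIMP3 and OLFML2B were higher after RK-287107. These 5 genes were taken from the called rises, so they do not show that stromal or matrix genes rose as a group. The metalloprotease genes MMP11 (-0.83 on its called probe set) and MMP2 (-0.67 on its brightest, not called) were lower. More host fibroblast RNA in the treated tumours is a candidate explanation. The fibroblast list had a median of 0.11, and camera did not call it (adjusted p = 0.055). The 95% bootstrap interval over its members ran from 0.0053 to 0.45, just above 0. Without COL1A2, which is in the list and in the pattern, the median was 0.08 (0.0023 to 0.25). Members of the list went both ways, with BGN at -0.73, and the other probe sets of the 5 genes past the filter gave 0.11 to 0.20 without a call. More host tissue of every kind stays open, because the endothelial median of 0.063 had an interval from -0.02 to 0.11 and the macrophage median of 0.10 one from 0.04 to 0.24. A rise within the human cells was not tested, as the array does not separate the species.

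Most called probe sets (84.4%) were lower after RK-287107. Normalization between arrays stays open. With quantile normalization 84.8% of calls were lower and with median centring 86.2%, which met the bound set in advance. These settings moved the median log2 fold change of all probe sets only from -0.0018 to 0.019 and -0.014, far less than the smallest called change of 0.46, and do not undo the scaling before deposit. Loss of intronic or non-coding signal stays open. Among 92 calls on protein-coding genes 80.4% were lower (exact binomial 95% interval 70.9% to 88.0%), against 93.0% of 43 calls on non-coding or unnamed probe sets. That interval treats probe sets as independent, though some genes have several, and does not measure the spread between mice. Intronic probe sets carry the name of their host gene and were not separated, so this split cannot decide. A general difference in RNA integrity is argued against by log2 differences in the 3' to 5' ratio of 0.020 for GAPDH and -0.013 for ACTB. These controls cover GAPDH and ACTB only, and a loss limited to other, less stable RNA was not tested. Over all tested probe sets, both treated arrays lay below the vehicle arrays in 24.5% and above them in 23.0%. The large excess of falls was thus seen among the called probe sets only. That the treatment lowers more of these transcripts than it raises is a hypothesis from the same data. Differences between the mice other than treatment were not tested.

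The Wnt list genes DKK4, DKK1 and GAD1 were lower after RK-287107. A lower share of human tumour cells would lower all transcripts of these cells alike, so by itself it would not set some of them apart. The upper 95% limits of all 3 genes lay at or below -0.74. The 12 measured pathway genes that were to be named whatever their values had a median of -0.066 (95% bootstrap interval -0.15 to 0.02). The 3 genes were taken because they were called, and none of the 12 was, so the choice of genes favoured this gap. Over the alternative fits the highest log2 fold changes of DKK4, GAD1 and DKK1 were still -1.37, -0.75 and -0.87. These values argue against a lower share of tumour cells as the sole source of the 3 falls. Scaling between arrays before deposit could hide a fall shared by all transcripts, but such a fall would not set the 3 genes apart. A loss of only those tumour cells that carry the 3 transcripts stays open. Of the 3 splits of the 4 arrays into pairs, 1 (the real one) called as many as 141 probe sets and the highest other called 0, and 3 splits are too few for a share under 0.05. An effect of the treatment on Wnt transcription remains open as a hypothesis.

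As a hypothesis, the lower SPRY2 and DUSP6 may go with lower ERK pathway output. ETV5, which was measured, was left out of the test because its value had been seen. The 16 other ERK feedback and target genes tested, 2 of which (EGR1 and CCND1) had also been seen before, had a median log2 fold change of 0.0061 (95% bootstrap interval -0.13 to 0.19). They went both ways, from MAFF at -0.50 to EGR1 at 1.26, none of them called, and the test left the hypothesis undecided.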
